A study of Mus musculus with 67 samples.

How the data were processed

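Single blastomeres of mouse embryos at the 8-cell stage were profiled by scRepli-seq, in which the whole genome of 1 cell is amplified and sequenced at low depth and the read density along the chromosomes is read as relative DNA copy number. The embryos were cultured in vitro and are labelled BDF1, the name of F1 hybrids of C57BL/6 and DBA/2 mice; whether the embryos or their parents were the hybrids is not given in the sources used here. They were exposed during the 4-cell stage to aphidicolin (75 ng/ml), an inhibitor of the replicative DNA polymerases, or to the solvent DMSO alone. The deposited metadata name the embryo of each of the 67 cells. DMSO comprised 20 cells of 3 embryos (4, 8 and 8 cells) and Aphidicolin 47 cells of 6 embryos, of which 5 gave 8 cells and 1 gave 7. Cells are called by treatment and library number, embryos by treatment and number. The embryo was the replicate. No paired analysis was possible because no cell or embryo number ties a DMSO sample to an Aphidicolin sample.

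The deposited tables hold log2 values for each cell, which the authors set relative to the median of that cell. The genome build was mm9, according to the submitters' processing notes; the aligner, the read filters and the step from reads to values are not given in the sources used here. The metadata also give a noise score per cell and pass or filter marks as a score of 1 or 0, deposited by the authors without a stated scale, and 2 further columns of other kinds (the embryo and the collection window), as names per the file headers. All 67 cells were marked as passing, 0 as manually filtered, and all shared 1 collection window, named as G1 to early S phase.

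Each table lists 13103 bins at steps of 200 kb. In each cell 100% of the values could be turned back into whole read numbers, within a tolerance of 0.01 reads, when bins 5 steps apart shared 1 median. In the 5 flattest cells the differences between neighbouring bins were correlated at between -0.07 and 0.08 for lags of 1 to 4 bins and at between -0.37 and -0.25 for a lag of 5 bins. The bins were therefore treated as 1-Mb windows that overlap their neighbours. The reads recovered this way came to between 1.49 and 2.88 M per DMSO cell (median 2.30 M) and between 0.751 and 2.69 M per Aphidicolin cell (median 2.05 M). The median window held between 269 and 1157 reads over the 67 cells, which at the median depth gives a counting error of 0.05 on the log2 scale. This error covers counting only, since amplified reads are not independent molecules. All intervals for shares also cover counting only. They take cells as independent, although cells of 1 embryo can share events, so they may be too narrow. A bin without a value in single cells was counted as 0 reads and set to a floor of 0.5 reads. Of the bins, 12836 were used.

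Values were summarised as medians over 1-Mb windows, 2397 on the 19 autosomes and 163 on X. A common profile, the mean of the medians of both treatments, was fitted to each cell by Huber regression and removed, to take out the pattern that the cells share. That pattern differed in size between cells, which argues against mappability as its only source. Whether it stems from replication timing, amplification or a mixture with mappability could not be settled here. The slope of a cell on the profile made without that cell is called the weight of the common profile. Change points were placed on each chromosome by penalised least squares, with a penalty of 4 times the noise variance times the logarithm of the number of windows and a minimum length of 10 Mb. Neighbouring segments within 0.35 on the log2 scale were merged. A segment was a gain above 0.32 and a loss below -0.42, the log2 values midway in copies between 2 and 3 and between 2 and 1. An event was whole-chromosome if called windows of 1 sign covered at least 90% of the chromosome and segmental otherwise; segments at different levels on such a chromosome count as separate events. A loss below -3 on the log2 scale is described as near 0 copies. Copies are 2 times 2 to the power of the log2 value, on the assumption that the median of the autosomes stands for 2 copies. Noise, as a measure per cell, is the scaled median absolute difference between neighbouring windows before removal of the common profile, so steps of that profile add to it. The noise variance in the penalty was taken after the removal. X was kept out of the calls.

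Differences between treatments were tested on embryo means by exact two-sided permutation over the 84 ways to split 9 embryos into 3 and 6, with Benjamini-Hochberg adjustment over 6 measures. The smallest p this design can give is 0.0119, or 0.0357 after adjustment when 2 of the 6 measures reach it. Opposite events in cells of 1 embryo (reciprocal overlap of at least 50%) were tested one-sided against 10000 shuffles of cells between embryos of the same treatment. Breakpoints with a breakpoint of another embryo within 2 Mb were counted and tested one-sided against 10000 random placements on the same chromosomes. Windows were compared between treatments with limma on embryo means of the log2 values as deposited, two-sided, at an adjusted p of 0.05. Intervals for shares of cells are exact 95% Clopper-Pearson intervals. These measures, limits, tests and most alternatives were fixed before the data were examined; the exceptions are named where their results stand.

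The named chromosomes, cells and regions follow a rule fixed at the same time. It takes the 5 autosomes with most called cells per treatment, ties included, and the 5 whole-chromosome and 10 segmental events with the largest absolute log2 value per treatment. It also takes the 10 opposite pairs with the largest overlap, the positions with breakpoints of at least 3 cells within 2 Mb, and the 5 highest and 5 lowest windows past the limma threshold. Of the positions only those shared by most cells are given one by one. Regions named outside this rule are said to be so. No genes are named, because no mm9 annotation was at hand.

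Alternatives to the minimum length, the call limits, the penalty, the common-profile fit, the overlap, the distance, the window size, the replicate unit and the set of embryos were run, as were alternatives added later. Calling was tested on events planted in the profiles of DMSO cells after removal of the common profile, and on simulated noise at the level of each cell. Of 100 planted events per kind, 93% of 10-Mb gains to 3 copies, 98% of 20-Mb and whole-chromosome gains and 100% of all losses of at least 10 Mb were called, and 67 cells of pure noise gave 0 calls. That noise was drawn independently for each window, so the 0 calls do not measure false calls in real profiles. The breakpoint test gave a p under 0.05 in 3 of 40 random sets. Those sets were placed evenly at random, as the test itself assumes, so they do not check that assumption for real breakpoints. With 200 of 2397 windows shifted between treatments, limma recovered 52.6% at a shift of 0.5 on the log2 scale and 89% at a shift of 1, with a mean of 6 and 9.75 false calls, and gave 0 calls without a shift. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used.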

Results

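The data were relative DNA copy number profiles of 67 single blastomeres from BDF1 embryos at the 8-cell stage. DMSO comprised 20 cells of 3 embryos and Aphidicolin 47 cells of 6 embryos. Between 0.751 and 2.88 M reads stood behind a cell, with a median of 2.30 M for DMSO cells and 2.05 M for Aphidicolin cells. Embryo means of depth were 2.25 ± 0.117 M reads for DMSO (SD, n = 3) and 1.99 ± 0.0964 M for Aphidicolin (SD, n = 6), a difference with an exact two-sided permutation p of 0.0238. X was at a median of -0.25 ± 0.05 relative to the autosomes on the log2 scale in DMSO embryos (SD, n = 3) and at -1.02 ± 0.07 in Aphidicolin embryos (SD, n = 6). These levels, 1.68 and 0.987 copies if autosomes are at 2, separated the treatments without overlap (exact two-sided permutation p = 0.0119), so that X number and treatment cannot be separated in any comparison of these embryos. Neither this test nor that of depth was among those fixed before the data were examined.

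The main comparison asks whether exposure to aphidicolin during the 4-cell stage goes with chromosome gains and losses in the blastomeres of the next stage. Autosomes of Aphidicolin cells carried many gains and losses, and those of DMSO cells few. On average 8.00 ± 1.94 of the 19 autosomes were aberrant per cell in Aphidicolin embryos (SD, n = 6) against 0.583 ± 0.520 in DMSO embryos (SD, n = 3). The embryo means ran from 5.88 in Aphidicolin 4 to 10.6 in Aphidicolin 3, and from 0 in DMSO 1 to 1 in DMSO 2. Aphidicolin cells 46, 47, 49 and 50, all of Aphidicolin 3, each had calls on 17 autosomes, and no DMSO cell had more than the 3 of DMSO cell 24. The rise of 7.42 autosomes had an exact two-sided permutation p of 0.0119 (adjusted p = 0.0357), the smallest that 3 and 6 embryos can give, and every Aphidicolin embryo lay above every DMSO embryo. Without removal of the common profile the difference was 0.0685 autosomes, with 11.1 called in Aphidicolin and 11 in DMSO. With any 1 DMSO embryo left out the difference was 7.10 to 7.65 autosomes, and the exact permutation p then cannot be below 0.0357 before adjustment.

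**Figure D1:**
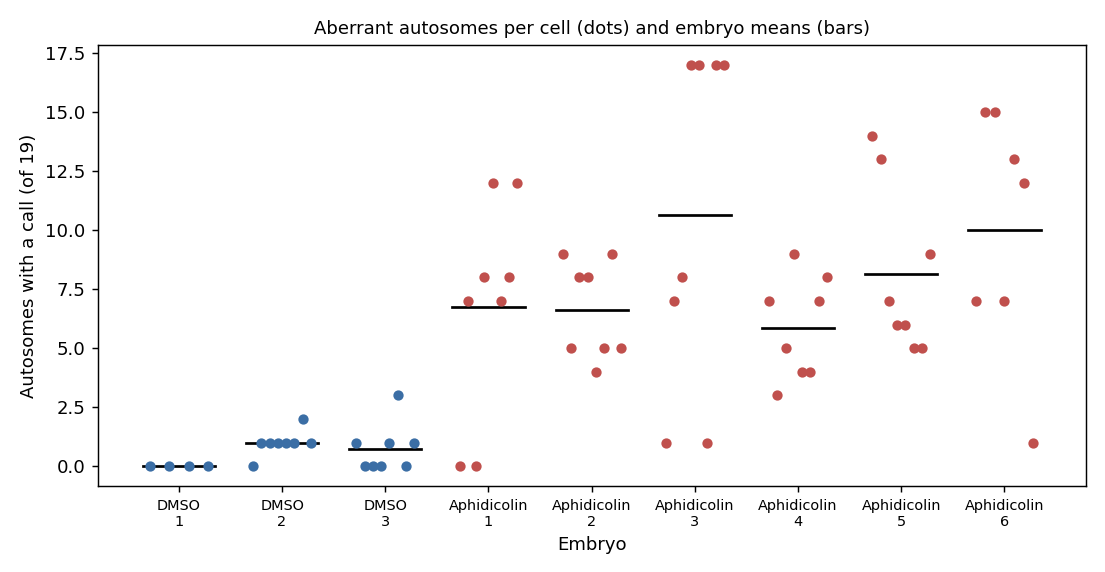
Number of autosomes with a call (vertical axis, of 19) in each of the 67 cells (dots), grouped by embryo (horizontal axis), with the mean of each embryo as a bar. DMSO cells reach at most 3 and Aphidicolin cells at most 17.

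Whole-chromosome events were found in Aphidicolin cells alone. In Aphidicolin embryos 77.1% ± 22.9 of cells (SD, n = 6) gained or lost at least 1 whole autosome, against 0% ± 0 in DMSO embryos (SD, n = 3). Pooled over embryos, 36 of 47 Aphidicolin cells (76.6%, 95% interval 62 to 87.7%) and 0 of 20 DMSO cells (upper limit 16.8%) carried one. Among the 95 whole chromosomes concerned, 45 were gained and 50 lost. The 5 largest such events were all losses to near 0 copies of the distal part of a chromosome whose proximal part was also lost, but to a lesser degree. They lay on chromosome 17 of Aphidicolin cell 46 (log2 -8.91), chromosome 2 of cell 35 (-8.49), chromosome 10 of cell 41 (-8.38), chromosome 9 of cell 31 (-8.24) and chromosome 12 of cell 51 (-8.17). The difference between treatments had an exact two-sided permutation p of 0.0119 (adjusted p = 0.0357), again the smallest possible. With values as deposited the difference was 75.0 points and the adjusted p 0.0714, because fewer of the 6 measures reached the smallest p.

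Aphidicolin cells also carried more gains and losses of parts of chromosomes, though DMSO cells were not free of them. Any aberration was present in 95.8% ± 10.2 of the cells of Aphidicolin embryos (SD, n = 6) and in 45.8% ± 43.9 of the cells of DMSO embryos (SD, n = 3). For segmental events the shares were 89.3% ± 12.4 and 45.8% ± 43.9. Pooled, 45 of 47 Aphidicolin cells (95.7%, 95% interval 85.5 to 99.5%) and 11 of 20 DMSO cells (55%, 31.5 to 76.9%) had a call, and Aphidicolin cells 27 and 29 had none. The exact two-sided permutation p was 0.0238 for any aberration (adjusted p = 0.0476) and 0.0476 for segmental aberrations (adjusted p = 0.0714), so the latter failed the correction. With 1 embryo left out in turn, any aberration kept an adjusted p under 0.05 in 1 of 9 cases, in which fewer splits also raise the smallest p; its difference of 50 points was 27.1 without DMSO 1 and 77.1 without DMSO 2, and that of segmental aberrations 20.5 and 70.5. Both differences vanished at a minimum length of 5 Mb, where 100% of the cells of both treatments were called, and turned to -4.17 and -6.55 points without removal of the common profile.

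In DMSO cells the calls were short and few. There were 14, all segmental, with a median length of 11 Mb, 5 of them gains and 9 losses, and without those that over 50% of the cells of an embryo share there were 7, with a median length of 23 Mb, 5 gains and 2 losses. Chromosome 12 had calls in 8 DMSO cells; in 7 of the 8 cells of DMSO 2 this was a 10-Mb loss, in DMSO cell 12 from 16000001 to 26000000 at a log2 of -0.74. Leaving out these shared events brought the DMSO cells with a call to 5 of 20 (25%, 95% interval 8.66 to 49.1%) and the embryo means of the share with a segmental aberration to 20.8% against 89.3% in Aphidicolin. This alternative was added after the data were seen; its exact two-sided permutation p was 0.0119 (adjusted p = 0.0179). Chromosome 8 had calls in 2 DMSO cells, a 16-Mb loss in cell 19 (log2 -0.58) and a gain of its proximal 79 Mb in cell 24 (log2 0.51). Chromosomes 3, 7, 14 and 17 had a call in 1 DMSO cell each, among them a 13-Mb loss on chromosome 7 in cell 17 (log2 -0.64).

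In Aphidicolin cells the 469 events, 215 gains and 254 losses, spread over all 19 autosomes. Chromosome 3 was called in 31 of 47 cells (66%) and chromosome 2 in 30 (63.8%), followed by chromosomes 1 and 12 with 25 cells each (53.2%) and chromosome 13 with 23 (48.9%). Chromosome 5 was called in fewest, 9 cells (19.1%). The count for chromosome 12 is 16 cells (34%) if events shared by over 50% of an embryo's cells are left out. Median levels were 0.57 for gains and -0.97 for losses on the log2 scale, close to those of 3 copies and 1 copy. The 340 segmental events had a median length of 47 Mb. No test ranked the chromosomes against each other, and longer chromosomes offer more room for a call.

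**Figure D2:**
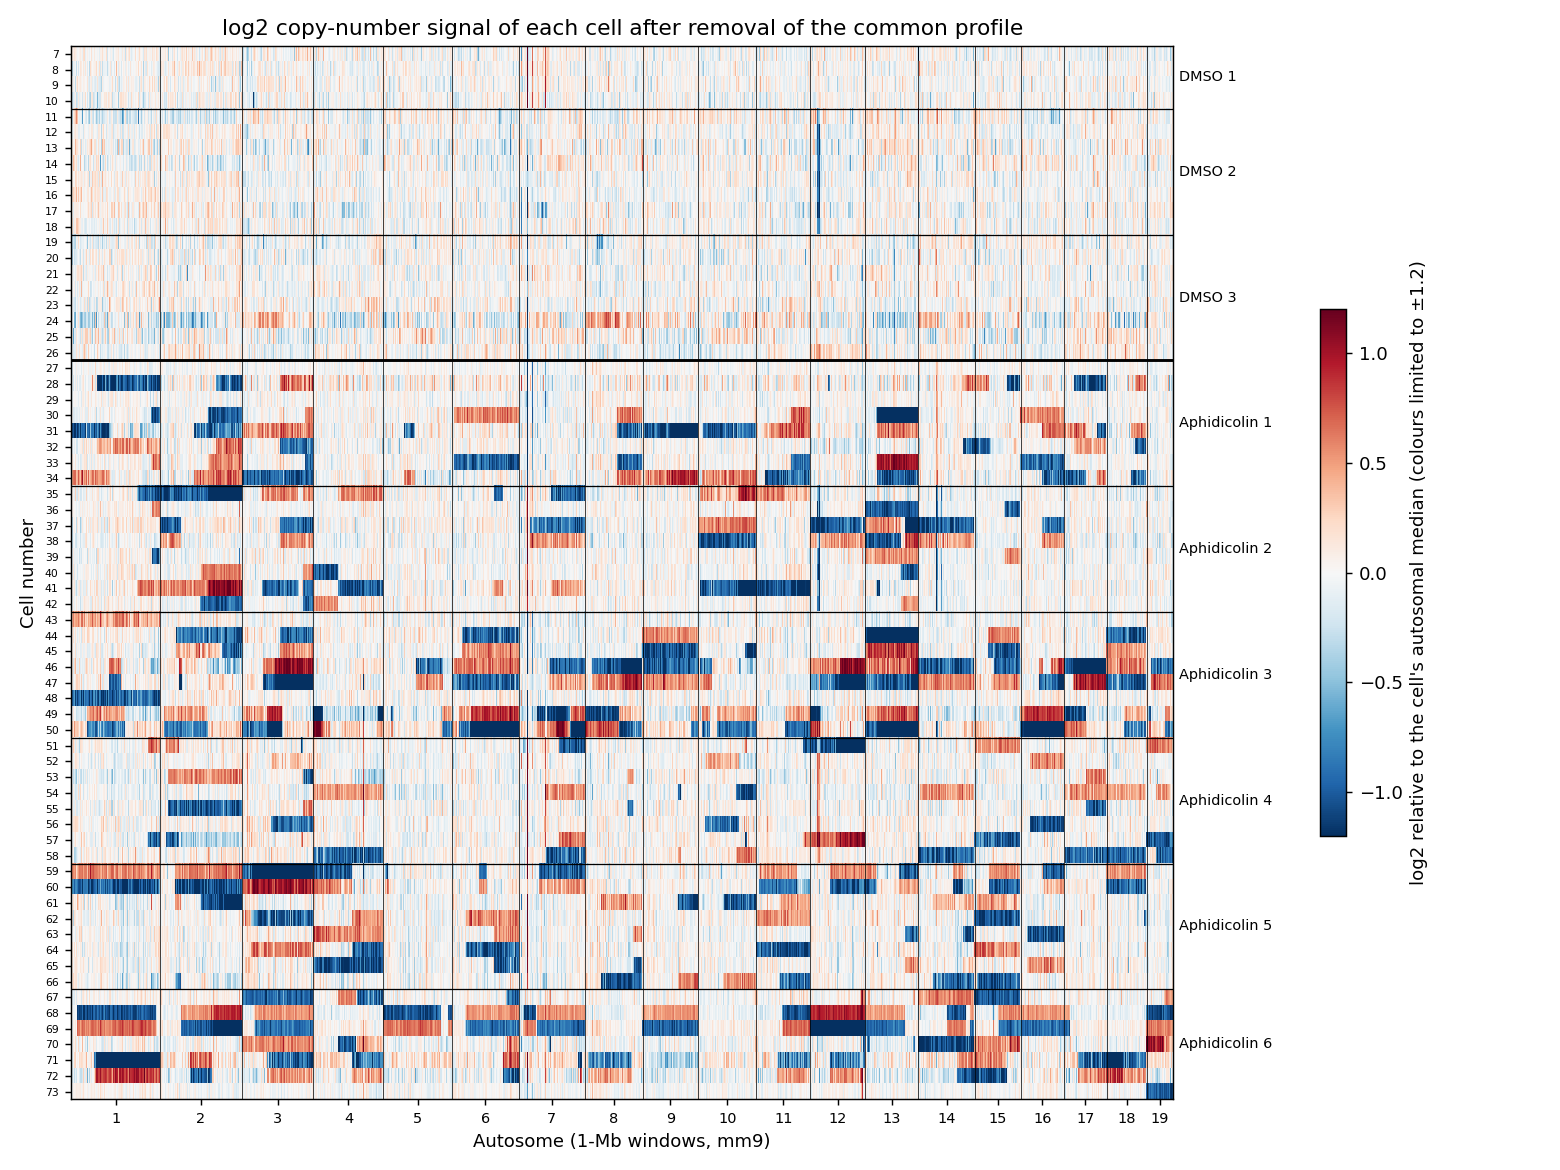
Copy-number signal (log2, colour, limited to ±1.2) in 1-Mb windows along the 19 autosomes (horizontal axis) in each of the 67 cells (vertical axis, grouped by embryo) after removal of the common profile. Red and blue blocks stand for gains and losses; there are 469 calls in Aphidicolin cells and 14 in DMSO cells.

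Some segments were missing from Aphidicolin cells almost completely. Among called segments, of at least 10 Mb and after removal of the common profile, 27 were near 0 copies, in 15 cells of all 6 Aphidicolin embryos, and none in the 20 DMSO cells (exact upper limit 16.8% of cells). Reads in them came to a median of 0.497% of the level at 2 copies and at most 3.57%. Among the 10 largest segmental events, all of them losses of this kind, were chromosome 13 from 92000001 to 120000000 in cell 37 (log2 -9.17) and chromosome 8 from 85000001 to 131000000 in cell 46 (-8.73). Others were chromosome 13 from 30000001 in cell 30 (-8.24), chromosome 1 from 57000001 in cell 71 (-8.11) and chromosome 2 from 119000001 in cell 69 (-7.71), each to the distal end. Cell 49 lacked the proximal 21 Mb of chromosome 4 (-7.75) and 19 Mb inside chromosome 7 (-7.69). Cell 61 lacked the distal 10 Mb of chromosome 9 (-7.65), and cell 50 the distal 105 Mb of chromosome 6 (-7.54) and 29 Mb of chromosome 7 (-7.31). High gains, above 0.81 on the log2 scale, numbered 23 in 15 Aphidicolin cells and 0 in DMSO cells.

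Gains and losses of the same segment often faced each other in cells of 1 Aphidicolin embryo. The largest such pair covered the whole of chromosome 1, gained in Aphidicolin cell 43 (log2 0.44) and lost in cell 48 (-0.92) of Aphidicolin 3. In Aphidicolin 6, cell 69 gained chromosome 1 from 17000001 to 187000000 (0.67) and cell 68 lost exactly that stretch (-1.04). Chromosome 2 from 21000001 was gained in cell 53 and lost in cell 55 of Aphidicolin 4, and from 36000001 gained in cell 59 and lost in cell 60 of Aphidicolin 5. Chromosome 3 was gained in cell 31 and lost in cell 34, and gained in cell 70 and lost in cell 67. Chromosome 4 was gained in cell 54 and lost in cell 58, and gained in cell 63 and lost in cell 65, and chromosome 6 was gained in cell 46 and lost in cell 47. The tenth pair was chromosome 1 from 55000001 in cell 72 (0.88), facing the loss to near 0 copies in cell 71. Of the 469 Aphidicolin events 405 (86.4%), in 45 of 47 cells, had an opposite event in another cell of the embryo. The share that shuffled embryos would give was not computed. Of the 14 DMSO events 0 had one, but shuffled DMSO embryos also gave at most 0 such pairs. The DMSO count is therefore no contrast to the 86.4%.

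The planned test of this relation did not pass. In Aphidicolin, 85 pairs of cells of 1 embryo held opposite events, against a mean of 79.2 when cells were shuffled between embryos (one-sided permutation p = 0.143). At a minimum length of 5 Mb the 85 pairs were fewer than the shuffled mean of 115. Counting pairs gives no weight to how many segments of 2 cells oppose each other. In a measure chosen after the data were seen, 42 of 47 Aphidicolin cells had their most opposite cell, the one with the lowest correlation of log2 values over windows, in their own embryo. Shuffled embryos gave a mean of 7.02 and at most 20 (one-sided permutation p = 0.0001, the smallest that 10000 shuffles can give). In DMSO the count was 0 of 20, against a shuffled mean of 6.49. Its upper limit of 16.8% takes cells as independent, which a choice of most opposite cells does not allow. With values as deposited the counts were 27 of 47 in Aphidicolin (shuffled mean 7.01) and 7 of 20 in DMSO (shuffled mean 6.53).

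**Figure D3:**
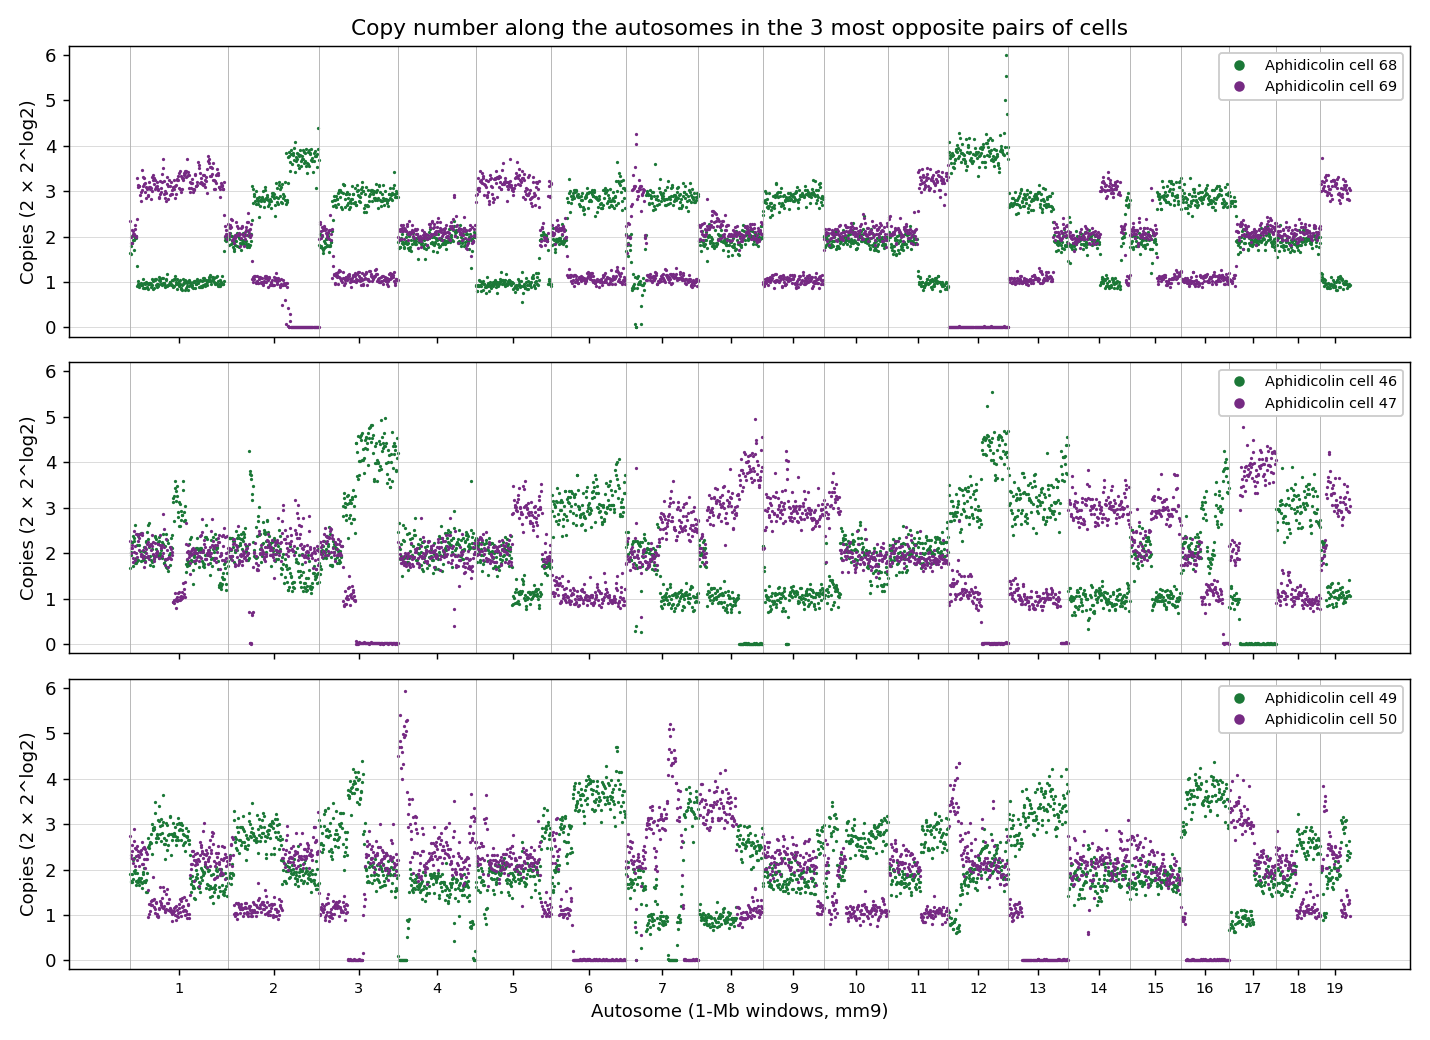
Copies (vertical axis, 2 times 2 to the power of log2, cut at 6) in 1-Mb windows along the autosomes (horizontal axis) in the 3 pairs of cells with the most negative correlation, Aphidicolin cells 68 and 69, 46 and 47, and 49 and 50, 1 colour per cell. Correlations across windows are -0.91, -0.85 and -0.84.

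Where breaks fell along the chromosomes was described by the breakpoints of segmental events. In Aphidicolin cells 181 of 397 breakpoints (45.6%) had a breakpoint of another embryo within 2 Mb, against 144 in random placements (one-sided permutation p = 0.0148). The placements took all positions as equally likely, so they make no allowance for any remainder of the common profile. There were 42 positions with breakpoints of at least 3 Aphidicolin cells, 27 of them in 2 embryos and 10 in 3. Opposite cells of 1 embryo often share a break, and the 397 breakpoints formed 217 sites when those of 1 embryo within 2 Mb were joined. Cells at a position are thus not independent breaks, and the number of such positions by chance was not computed. The most shared were on chromosome 12 at 16000000 to 18000000 (9 cells of 2 embryos) and 25000000 to 27000000 (9 cells of 3 embryos). These are near the bounds of the strip lost in cells of DMSO 2; it was lost in cells of Aphidicolin 2 and gained in cells of Aphidicolin 4, such as cell 52 (log2 0.43). Next came chromosome 13 at 28000000 to 30000000 (7 cells of Aphidicolin 1, 2 and 5). Of the positions with 6 cells, those on chromosome 13 at 91000000 to 92000000, chromosome 17 at 51000000 to 52000000, chromosome 2 at 49000000 and chromosome 3 at 86000000 came from 3 embryos each. Those on chromosome 2 at 36000000 to 38000000, chromosome 3 at 136000000 to 137000000 and chromosome 4 at 57000000 and at 87000000 to 88000000 came from 2 embryos each. In DMSO cells 8 of 24 breakpoints were shared (one-sided permutation p = 0.0402), but 0 without DMSO cell 26, and both recurrent positions were the bounds of the chromosome 12 strip. Without events shared by over 50% of an embryo's cells, 161 Aphidicolin breakpoints remained near another and the permutation p was 0.0568; with stricter call limits the p was 0.0561 and with a distance of 5 Mb it was 0.275.

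Whether any region shifted in most embryos was asked with limma on 2397 windows. Gains and losses that face each other in cells of 1 embryo partly offset each other in its mean. The test therefore cannot show whether such events recur in a region. No window passed (0 at an adjusted p of 0.05, lowest adjusted p 0.557), and 190 had an unadjusted p under 0.05. With called chromosomes set to missing 0 passed as well, but 625 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0707. The median difference of all windows, Aphidicolin minus DMSO, was -0.08 on the log2 scale. The largest differences, chosen by size after none had passed, were higher values at chromosome 7 from 21000001 to 24000000, by 1.89 ± 2.23 (SE) in its middle window, and on chromosome 3, by 0.40 ± 0.15 (SE) from 15000001 to 16000000 and 0.33 ± 0.10 (SE) from 12000001 to 13000000. In both chromosome 3 windows 5 of 6 Aphidicolin embryos lay above all DMSO embryos, and with called chromosomes set to missing the differences were 0.52 and 0.43 (limma adjusted p = 0.0707 each). Lower values lay on chromosome 13, by -0.81 ± 0.50 (SE) in the window from 114000001 to 115000000, where 5 of 6 Aphidicolin embryos lay below all DMSO embryos; with called chromosomes set to missing this difference was -0.05. A fit to single cells with the embryo as a random block called 4 windows, all higher in Aphidicolin and all on chromosome 5, at 16000001 to 18000000 (0.28 and 0.29), 82000001 to 83000000 (0.29) and 133000001 to 134000000 (0.23). The correlation within embryos in that fit was -0.03, so it treated the 67 cells almost as independent replicates.

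Cells shared a profile of highs and lows along the chromosomes, of a nature not settled here, to differing degrees. The weight of this common profile was 0.804 ± 0.293 in Aphidicolin embryos (SD, n = 6) and 1.22 ± 0.102 in DMSO embryos (SD, n = 3). It was under 0.5 in 13 of 47 Aphidicolin cells and in 0 of 20 DMSO cells (upper limit 16.8%), with the lowest value, -0.129, in Aphidicolin cell 73 and the highest, 1.39, in DMSO cell 15. Aphidicolin 6 had the lowest embryo mean, 0.337. The difference had an exact two-sided permutation p of 0.0595 (adjusted p = 0.0714). Noise between neighbouring windows was 0.177 ± 0.0335 in Aphidicolin (SD, n = 6) and 0.218 ± 0.0105 in DMSO (SD, n = 3, exact two-sided permutation p = 0.0952, adjusted p = 0.0952). It was taken before removal of the common profile and so is not separate from its weight. Neither difference passed the test over embryos. Mappability is the same in every cell and alone would give all cells similar weights. The range of weights from -0.129 to 1.39 argues against it as the only source of the profile.

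**Figure D4:**
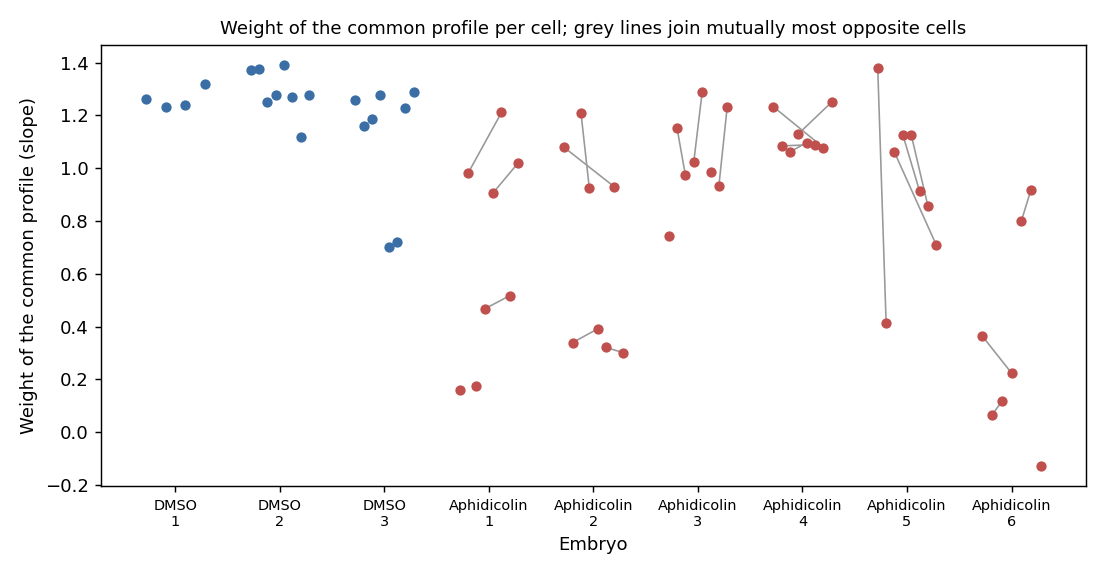
Weight of the common profile (vertical axis, slope) in each of the 67 cells (dots), grouped by embryo (horizontal axis), with grey lines joining the 21 pairs of mutually most opposite cells. DMSO cells lie between 0.70 and 1.39 and Aphidicolin cells between -0.129 and 1.38.

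**Figure D5:**
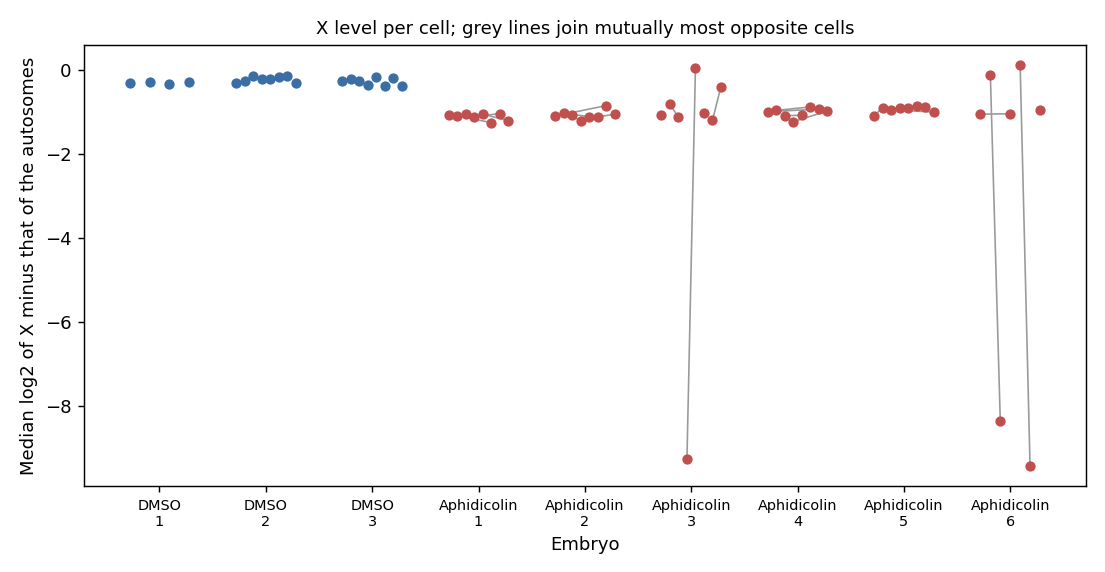
Median of X minus that of the autosomes (vertical axis, log2) in each of the 67 cells (dots), grouped by embryo (horizontal axis), with grey lines joining mutually most opposite cells. DMSO embryos have medians between -0.30 and -0.20 and Aphidicolin embryos between -1.09 and -0.90.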

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

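The test of the deposited values was set before its result was seen; the tests on boundary positions, copies in the opposite cell, noise, depth, X number and strips were chosen only after the result was seen. Of these, those on boundary positions, copies, noise, depth and the chromosome 12 strip replaced an earlier form that had been run first.

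Cells of 1 Aphidicolin embryo formed mirror images of each other: 21 pairs of cells were mutually most opposite, between 3 and 4 in each of the 6 embryos, with correlations across windows from -0.91 to -0.35. The fit of the common profile as the cause is argued against, since with values as deposited 27 of 47 cells still had their most opposite cell in their own embryo, against at most 24 in shuffled embryos. Uneven amplification of single cells is argued against by the boundaries of opposite events. With the pairs chosen on the other chromosomes, 79.2% of 202 lay within 1 Mb of each other (79.9% with pairs chosen on all windows). For the most opposite cell of another embryo it was 17.9% of 28. Pairs of 1 embryo had to be mutually most opposite, those with another embryo only in 1 direction, here and for the copies that follow. Without any choice of pairs, 54.7% of 331 lay so close in cells of 1 embryo and 9.04% of 852 in cells of different embryos. Where a cell had near 0 copies, the opposite cell chosen on the other chromosomes had a median of 3.80 copies (3.32 to 4.70 over 27 segments), against 2.01 in the most opposite cell of another embryo. A candidate explanation is that the pairs are daughter cells of 1 division that shared chromosomes and fragments unequally; the labels name no sisters, so this remains a hypothesis found and tested on the same data.

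Aphidicolin cells had more aberrant autosomes, 8.00 on average per embryo against 0.583. Noise in DMSO libraries hiding large events was not decided by chromosome medians. A median beyond a limit always brings a call on that chromosome, so the count of 0 uncalled DMSO medians was fixed in advance. Of 380 DMSO medians 0.263% lay beyond the limits, and the 1 concerned was called, against 24.2% of 893 in Aphidicolin. An earlier form of the test, which allowed no DMSO median beyond the limits, had not decided either. Gains of 10 Mb planted in DMSO profiles after removal of the common profile were called in 93% of cases and losses in 100%. This argues against the noise left after that removal hiding events of that size. Whether the removal itself weakens events was not tested. For lower depth, the 44 Aphidicolin cells within the depth range of DMSO cells had embryo means from 5.88 to 11.1, against at most 1 in DMSO embryos. That range kept 44 of 47 cells, so it matched depth only loosely. The 9 Aphidicolin cells at least as deep as the median DMSO cell had a median of 6 aberrant autosomes. Their lowest value was 0, and no DMSO cell had more than 3. These values argue against lower depth as the whole cause, though the deep cells are few. An earlier form on embryo depth had only 1 Aphidicolin embryo in range. The number of X chromosomes cannot be told apart from the treatment, because the X level split all 9 embryos as the treatment did, and its cause, whether sex or another difference between the sets of embryos, was not tested. The treatment may therefore account for the difference, but so might any feature that goes with the X level.

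In 2 strips of the genome, picked because cells of 1 embryo looked alike there, embryo medians differed. At chromosome 7 from 21000001 to 24000000 they were near 0 copies in Aphidicolin 1, Aphidicolin 3, DMSO 2 and DMSO 3 (log2 between -7.54 and -4.86) and between -1.26 and 0.00 in the others, with 85.4% of the variance between embryos, although cells of Aphidicolin 6 ran from -10.66 to 0.56. At chromosome 12 from 17000001 to 25000000 the share was 90.1% in DMSO cells but 28.5% over all cells, below the highest shuffle of 31.1%, and cells of Aphidicolin 3 ran from -1.28 to 1.55 and of Aphidicolin 6 from -7.42 to 0.99. The treatment as the cause is argued against by DMSO 2, at -0.56 in this strip, near Aphidicolin 2 at -0.60 while DMSO 3 was at 0.54, and a strain variant in embryos that are all F1 hybrids by the 1.64 copies between DMSO embryos on chromosome 7, since such embryos would have 1 genotype. A variant that segregates, as in offspring of BDF1 parents, may be the cause but is untested: the labels do not give the parents' genotypes, and the shares of variance restate how the strips were picked.

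Of 42 groups of cells or embryos tested for a member far from the rest, 4 had one, and chance gives about 1 in 20. Aphidicolin 1 lay apart from the other 5 Aphidicolin embryos, with 75% of its cells aberrant against 100%. Aphidicolin cell 59 had a noise of 0.255, far from the other cells of Aphidicolin 5. DMSO cell 24 had 3 aberrant autosomes, far from the rest of DMSO 3.

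X was kept out of the calls, and 7 Aphidicolin cells deviated there from their embryo by more than 0.5 on the log2 scale, where no DMSO cell deviated by more than 0.132. X was near 0 copies in cell 46 (-9.28), which also lay far from the other cells of Aphidicolin 3, in cell 69 (-8.36) and in cell 72 (-9.44). It was higher than in the rest of the embryo in their most opposite cells, 47 (0.0632), 68 (-0.11) and 71 (0.13), and in cell 50 (-0.39), whose most opposite cell 49 was at -1.19.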

How the results depend on the processing

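Alternatives added after seeing the data were the left-out embryo-wide events, alone or with stricter limits, each treatment's own profile, non-overlapping windows, missing bins, the left-out DMSO cells, the most opposite cell and each left-out Aphidicolin embryo. Values are Aphidicolin minus DMSO, and the cause of a change was not tested unless given. For any aberration, 8 of 13 alternatives kept direction and side of the threshold. The difference became 0 points at a minimum of 5 Mb and -4.17 without the common-profile fit, and its adjusted p was above 0.05 with stricter limits (60.4), a penalty factor of 2 (45.8) and non-overlapping windows (50). For segmental aberrations it became 0 at 5 Mb and -6.55 without the fit, and passed the threshold at 20 Mb (72.6), without embryo-wide events (68.5), without them and with stricter limits (85.1), and with cells pooled (34.4), which treats cells of 1 embryo as independent. Whole-chromosome aberrations (75.0) and aberrant autosomes (0.0685) lost the threshold without the fit and kept it in the other 12 alternatives. Pooling cells also brought noise (-0.0371) and the weight of the common profile (-0.397) past it. Clustering of breakpoints lost its threshold at a distance of 5 Mb (251 breakpoints), with stricter limits (151) and without embryo-wide events (161), and kept it in 4 of 7. Among these 4 was the setting without the common-profile fit (656 of 847 breakpoints). Its calls include steps of the shared profile, which recur between embryos in any case, so it lends no support. Clustering of breakpoints of DMSO cells was 0 without DMSO cell 26. Opposite events stayed short of it in 5 of 6 settings, turned to fewer pairs than chance at 5 Mb (85 against a shuffled mean of 115) and passed it as the count of most opposite cells (42). The random block gave 4 windows, limma's other settings 0.

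Leaving out 1 embryo in turn gave 27.1 to 77.1 points for any aberration, 20.5 to 70.5 for segmental and 72.5 to 82.5 for whole-chromosome aberrations. It gave 6.87 to 7.82 aberrant autosomes, -0.0486 to -0.0311 for noise, -0.481 to -0.322 for the weight and 0 windows (65 to 297 at an unadjusted p under 0.05). For any aberration the lowest value came without DMSO 1 and the highest without DMSO 2. Whole-chromosome aberrations and aberrant autosomes kept their direction in 9 of 9 and their adjusted p in 1 of 9; the smallest adjusted p that 2 of 6 measures can reach is then 0.0536 or 0.107, so fewer splits are the cause.

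With limma the real split gave 0 windows, which 84 of 84 splits of the 9 embryos reach by definition, so that this count says nothing about chance. At an unadjusted p under 0.05 it gave 190 windows; 13 of 84 splits, the real one included, gave as many, so chance cannot be excluded, and the highest other gave 620. At the adjusted threshold the highest other split, Aphidicolin 3, 4 and 6 against the rest, gave 48 windows; what sets these embryos apart was not tested.

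The named collection window and the authors' quality marks could not be varied, since all cells share them. The cell-cycle state of each cell within that window was not tested. No calls by the authors were used here. The noise filter removed 0 cells and so gives no value. Depth limits single windows to steps well above 0.05 on the log2 scale, and gains of 10 Mb are called less surely than losses.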

Other observations

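Both tests in this part, on the ends of segments and on the common profile in mirror pairs, were chosen only after the result was seen.

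Segmental events of Aphidicolin cells lay mostly at the far end of the chromosome. Mouse autosomes have their centromere at the proximal end. Without events shared by over 50% of an embryo's cells, 210 of 331 segments reached the distal end, 38 the proximal end and 83 neither. Distal segments outnumbered proximal ones in each embryo, with 39 against 6 in Aphidicolin 1, 44 against 14 in Aphidicolin 3 and 22 against 0 in Aphidicolin 4 (6 of 6 embryos, exact two-sided sign test p = 0.0312). Of the 7 such segments in DMSO cells, 0 were distal and 4 proximal, 3 of them in DMSO cell 24. Breaks that leave the part next to the centromere in place may give such counts, but the 6 of 6 embryos are the observation that raised this explanation, so it was not tested.

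Mutually most opposite cells resembled each other in the common profile. With called chromosomes left out, the weight of the profile differed by a mean of 0.147 in the 21 pairs, against 0.297 when cells of an embryo were paired at random (one-sided permutation p = 0.0031). Opposite cells often had calls on the same autosomes, so their weights rest on much the same remaining chromosomes. This can lower the difference in pairs but not in random ones. With all chromosomes the weight differed by 0.194 against 0.304 (one-sided permutation p = 0.0114). Read numbers showed no such likeness, with a mean difference of 0.408 M against 0.417 M (one-sided permutation p = 0.398). In Aphidicolin 6, cells 68 and 69 had weights of 0.0649 and 0.116, and in Aphidicolin 2, cells 40 and 42 had 0.321 and 0.301; the pair of cells 59 and 60 in Aphidicolin 5 was far apart, at 1.38 and 0.415. Daughter cells at the same point of DNA replication could give this likeness of 0.147, but whether the profile reflects replication at all was not settled, and handling of both cells together stays open, as untested.

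No 2 cells had identical values (0 pairs), and the highest correlation across windows after removal of the common profile, 0.608, was between Aphidicolin cells 27 and 29, the pair without calls.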
